A study of Mus musculus with 20 samples.

How the data were processed

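The series holds poly(A) RNA-seq of mouse M-MDSC and PEC, 8 libraries each (wild type and p50 knockout, untreated and interferon-gamma, 2 libraries per group), and STAT1 ChIP-seq of PEC, 1 library per genotype and treatment. Per the labels' protocols, M-MDSC came from mice bearing a fibrosarcoma for 28 days, by removal of CD19 and CD11c positive cells, selection of Ly6G positive cells and CD11b selection of the remainder, with a purity above 90%, and PEC came from mice given thioglycollate. The same protocols give 4 h of culture with or without 200 U/ml interferon-gamma. The titles were used for the groups. A treatment entry in the labels contradicts the titles of 4 of the 8 M-MDSC libraries, and it was used for an alternative grouping.

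Per the submitters' processing notes, reads were converted with bcl2fastq, RNA reads were aligned to mm9 with TopHat 1.3.1, counted with HTSeq and handled with edgeR, and ChIP reads were aligned with Bowtie and peaks called with MACS 1.4. The authors deposited 1 table per cell type of CPM (reads of a gene per 1000000 counted reads) for 23282 genes. Every deposited CPM value is a whole multiple of a step per library, within 0.01 of a read, so the count of reads behind each value was recovered from the deposited table by dividing by the step. For treated knockout M-MDSC replicate 1 that step, 0.0999614, lies close to 0.1, which could also come from rounding. Rounding to 0.1 would leave values at whole multiples of 0.1, and a value of 0.299884 CPM for 3 reads argues against it. Its recovered reads also sum to the total that the step gives, 10003858. The libraries held 9.50 to 15.1 M reads (M-MDSC; M, 1000000) and 24.3 to 27.8 M (PEC), and a floor of 3 reads corresponds to 0.199 to 0.316 CPM and to 0.108 to 0.123 CPM. The 10 most abundant genes took 16.1 to 19.5% of the M-MDSC reads and 12.2 to 15.5% of the PEC reads. The PEC workbook has 3 sheets with equal values, of which 1 was used, and 25 of its gene names had been turned into dates and were left out of comparisons between tables, which leaves 23257 shared names. Of the M-MDSC symbols 21085 are current, 2000 are older names and 197 were not matched. All genes were tested under the deposited name.

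Each peak list gives, per the file headers, the tag count of a peak, a score that is the negative log10 of the peak p-value times 10, a fold enrichment ratio over the local background and a false discovery rate in percent, made by MACS 1.4.0beta with a p-value limit of 1e-05, a tag size of 36 bp and a band width of 100 bp. The deposited p-value scores and fold ratios were used as they stand, and the deposited percent false discovery rate was read but used for no selection. The authors' filtered tag counts were 18172032, 20491860, 18841828 and 23192283 for untreated and treated wild type and untreated and treated knockout, against 6295514 tags of 1 shared input. Coordinates are mm9. The gene annotation given is for another assembly, so no peak was assigned to a gene.

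The tests across genes used limma 3.58.1 in R 4.3.3 on log2(CPM + 0.5), for genes with at least 1 CPM in at least 2 libraries of the table (11015 in M-MDSC, 11242 in PEC). A model of the 4 group means was fitted per table, with contrasts for interferon-gamma in each genotype, for genotype in each treatment, and for their interaction (the knockout response minus the wild-type one), empirical Bayes moderation with a trend, and Benjamini-Hochberg adjustment. A gene is called at an adjusted p under 0.05. The tables were normalized separately, so levels were not compared between cell types. These choices, the gene lists and the rule for named genes were fixed before the data were examined. The gene lists (29, of which 23 per cell type had at least 5 tested genes) were tested with camera at a preset correlation of 0.01, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. Member counts are given at the threshold over all genes and with p-values adjusted over the list alone. The rule names Nfkb1 first, then up to 8 called genes per direction with the largest fold changes, no overlap between the libraries of the groups and at least 10 CPM in the higher group, then 4 members with the smallest adjusted p of each described list and 14 fixed genes (Nos2, Tnf, Il12b, Arg1, Cxcl9, Cxcl10, Ptgs2, Il10, Il6, Il1b, Stat1, Irf1, Ccl2 and Cd274), skipping unnamed gene models. Of the fixed genes, Il6 and Il12b were under the filter in both tables and Il10 and Il1b in PEC. A gene with 0 reads in a group is given as a bound, with 3 reads in that group, and a gene with 1 to 3 reads as a read ratio with a 95% binomial interval, which covers counting error alone and not the spread between libraries.

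Alternatives to the main test were other added constants (0.1 and 2 CPM), other filters, median-of-ratios and quantile scaling, a replicate block, a fold threshold, robust moderation, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, the compared groups alone, each library left out, and, added after the data were seen, both libraries of knockout M-MDSC replicate 2 left out. Calls shared between comparisons were tested with a two-sided Fisher's exact test over the 10326 genes tested in both tables. Peak lists were compared with bedtools 2.31.1 (at least 1 shared bp), with the same peaks moved by 100 kb as background, and tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The test was tried on simulated data with planted changes between untreated knockout and wild type. With the spread of the M-MDSC tables it found 5 of 67 changes of 1.5-fold, 26 of 67 of 2-fold and 59 of 66 of 4-fold, with 7 false calls among 97, and with that of PEC 55 of 67, 62 of 67 and 66 of 66, with 17 false calls among 200. The simulated libraries were independent, with 1 spread per gene for all groups. In M-MDSC the knockout replicates differed more (chi-square per gene of 34.5 untreated and 38.1 treated) than the wild-type ones (9.03 and 11.4). The M-MDSC shares found and false calls may therefore not hold for the real libraries.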

Results

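The series asks how loss of p50, the NF-kB subunit encoded by Nfkb1, changes myeloid cells and their response to interferon-gamma. Monocytic myeloid-derived suppressor cells (M-MDSC), immature monocytes that build up in tumour-bearing mice and can restrain T cells, were taken 28 days after injection of a fibrosarcoma and enriched magnetically to a purity above 90%. Peritoneal exudate cells (PEC), rich in recruited macrophages, were taken 4 days after an injection of 3% thioglycollate. Wild-type and p50 knockout cells were cultured for 4 h, untreated or with 200 U/ml interferon-gamma. Poly(A) RNA was sequenced in 2 libraries per group, 8 from M-MDSC and 8 from PEC. Chromatin bound by the interferon-activated factor STAT1 was sequenced in 1 library for each of the 4 PEC groups. The M-MDSC RNA libraries held 9.50 to 15.1 M gene-assigned reads (M, 1000000) and the PEC libraries 24.3 to 27.8 M. S100a8 or Ngp, abundant in granulocyte-lineage cells, was the most abundant transcript of every M-MDSC library, and Psap, a lysosomal protein precursor, that of every PEC library. Ltf† and Lcn2†, also granulocyte markers, were among the 10 most abundant of every M-MDSC library. The M-MDSC values may thus include RNA of granulocyte-lineage cells. Group values below are mean ± SD in CPM (reads scaled to a library total of 1000000, n = 2). Fold changes are on the scale log2(CPM + 0.5), which understates the change of low genes. The labels do not state that the libraries of a group came from separate animals or cultures, so the p-values measure only the spread between these libraries. A dagger (†) marks a gene outside the fixed rule for named genes, chosen after its values were seen.

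Nfkb1 was lower in every knockout library than in every wild-type library of the same cell type. In M-MDSC the untreated wild-type libraries held 138 and 156 CPM and the treated ones 233 and 231, against 65.8 and 70.0 in the untreated and 92.2 and 97.0 in the treated knockout. In PEC the values were 71.7 and 70.8 and 138 and 126 in the untreated and treated wild type, and 25.6 and 29.1 and 45.9 and 44.4 in the knockout. The knockout difference on the log2 scale was -1.11 ± 0.14 (SE) in untreated M-MDSC (limma adjusted p = 0.0095). It was -1.37 ± 0.07 in untreated PEC (limma adjusted p = 9.8e-06). With interferon-gamma it was -1.29 (adjusted p = 0.011) and -1.54 (adjusted p = 2.9e-06). The values are totals per gene and do not show which part of the gene the remaining reads came from. Of the 7 genes flanking Nfkb1, 0 passed limma in M-MDSC, untreated (1 lower adjusted over the list alone) or treated (0 adjusted over the list alone), although as a list they had a median of -0.41 in treated cells (camera adjusted p = 0.0091, adjusted p = 0.65 with an estimated correlation). Of the 11015 genes tested in M-MDSC, 721 untreated and 752 treated had an unadjusted p under 0.05 between genotypes. By chance alone a share of 0.05 of the tested genes would have one. In untreated PEC 1 of the 7 was lower, Cisd2, at a log2 fold change of -0.25 (3 higher and 2 lower adjusted over the list alone).

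**Figure D1:**
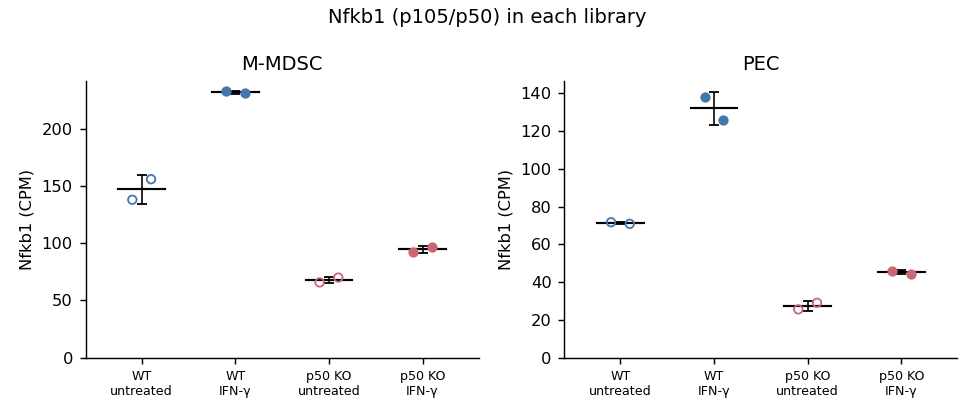
Nfkb1 in each library, in CPM, for the 4 groups of M-MDSC (left) and of PEC (right), with single libraries as circles (open: untreated, filled: interferon-gamma) and bars for mean and SD (n = 2). The knockout libraries lie below all wild-type libraries of the same cell type, at means of 67.9 and 94.6 CPM in M-MDSC and 27.3 and 45.1 CPM in PEC.

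Interferon-gamma raised the GTPases of the GBP and IRG families, which act against intracellular pathogens, in wild-type M-MDSC. All 18 measured members rose (18 adjusted over the list alone), with a median log2 fold change of 8.09, the largest of the lists. Gbp2 went from 3.80 ± 0.36 to 9959 ± 465 CPM, a log2 fold change of 11.18 ± 0.23 (SE; limma adjusted p = 7.4e-09). Gbp5, Ifi47 and Igtp rose by 10.36, 8.35 and 7.09 log2 units. Cxcl9, a chemokine that attracts activated T cells, had 0 reads in both untreated libraries and 580.2 ± 217 CPM after treatment, at least 4818-fold higher against 3 reads over the group. Gbp6 also had 0 reads before treatment and was at least 1874-fold higher after it. Cxcl10, a chemokine acting on the same receptor, rose from 1.25 ± 0.68 to 1046 ± 213 CPM. Reads of near-identical copies in these families (the Gbp, Tgtp and Serpina3 genes) can be split in counting, so values of single members are uncertain. Serpina3g reached 772 ± 61 CPM, 9803 times the untreated level with an interval of 2713 to 80950 from 2 untreated reads (here and below, such intervals cover counting error alone). Tgtp2 reached 435 ± 40.2 CPM, 11031 times the level of 1 untreated read, with an interval of 1979 to 435758. Iigp1, of the same GTPases, rose by 9.36 log2 units.

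The other interferon lists of wild-type M-MDSC moved the same way. Of 25 type I interferon-stimulated genes, which encode antiviral proteins, 23 rose (24 adjusted over the list alone; median 4.24), among them Zbp1, Rtp4, Oas2 and Oasl1. In the list of interferon signalling and transcription 16 of 20 rose and 1, the receptor gene Ifngr1†, fell (16 and 1 adjusted over the list alone; median 2.85). Stat1, which carries the interferon signal to the nucleus, went from 120.5 ± 1.9 to 1751 ± 95 CPM, and the transcription factor gene Irf1 rose by 4.64 log2 units (adjusted p = 7.6e-08). All 16 genes of MHC class I presentation, which shows peptides to CD8 T cells, rose (16 adjusted over the list alone; median 2.69), as Tap1 did by 3.65 and Psmb9 by 3.27. Of 18 interferon chemokines and T-cell ligands 15 rose (15 adjusted over the list alone), with a median of 2.37, or 2.84 with genes at 0 reads placed at their bound. Cd274, the T-cell inhibitory ligand PD-L1, rose by 3.83 (adjusted p = 1.9e-06). These 5 lists passed camera with the preset correlation and with an estimated one.

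Inflammatory genes rose as well in wild-type M-MDSC, with weaker support as groups. Of 27 NF-kB inflammatory targets 20 rose (20 adjusted over the list alone; median 1.21; camera adjusted p = 8.1e-17, adjusted p = 0.12 with an estimated correlation). Among them were Tnf, an inflammatory cytokine (91.9 ± 17 to 446 ± 56 CPM), Il1b (log2 fold change 2.64) and Icam1 (3.11). In the NF-kB and IkB family 7 of 14 rose (8 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00057, adjusted p = 0.20 with an estimated correlation), Nfkb1 itself by 0.66. In the list of nitric oxide, arginine and suppressor effectors 5 of 22 rose and 2 fell (5 and 3 adjusted over the list alone; camera adjusted p = 0.0020, adjusted p = 0.078 with an estimated correlation). Nos2, the inducible nitric oxide synthase, rose from 0.310 ± 0.032 to 56.6 ± 1.6 CPM and Slc7a2, an arginine transporter, by 2.68 log2 units. Cd274, Entpd1 and Il4ra† also rose, and Vegfa† and Ncf2† fell. Arg1, which breaks down arginine, did not pass the test (1.29 ± 0.61 and 2.23 ± 2.7 CPM, adjusted p = 0.88), nor did Il10 (log2 fold change 0.24) or Ccl2 (1.25). In the prostaglandin E2 pathway, Ptgs2 (cyclooxygenase-2), Pde4b, Crem and Ptges3† rose and Ptger2 fell, of 12 genes (5 and 2 adjusted over the list alone), with a median of -0.08 and a mean of 0.50 (camera adjusted p = 0.028, adjusted p = 0.37 with an estimated correlation, 0.064 after median-of-ratios scaling). Ptgs2 went from 0.472 ± 0.0097 to 21.3 ± 4.0 CPM. MHC class II presentation rose in 2 of 8 genes, Ciita and H2-DMa (2 adjusted over the list alone; camera adjusted p = 0.0050, adjusted p = 0.42 with an estimated correlation). Among monocyte identity genes 5 of 21 rose and 2 fell (7 and 3 adjusted over the list alone), Plac8 and Fcgr1 upward and Cx3cr1, the fractalkine receptor, downward (32.9 ± 1.6 to 1.25 ± 0.77 CPM, -4.33). The fall of Cx3cr1 was the largest among the genes ranked by the rule for named genes. Gpr183, an oxysterol receptor, Thbs1, the integrin gene Itga6, St6gal1, Cd101, Nav1 and Pdcd4 fell by 3.84 to 2.72 log2 units.

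Over all 11015 tested genes of wild-type M-MDSC, 766 rose and 1396 fell, 564 and 603 of them by 2-fold or more. Median-of-ratios scaling moved the median gene by 0.23 log2 units and gave 977 higher and 557 lower, so the split of small changes rests on the deposited scaling. Without 1 library at a time the total of 2162 became 703 to 1054 genes, and a fit of the compared groups alone gave 4290.

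Interferon-gamma raised these interferon lists in knockout M-MDSC too. All 18 GBP and IRG GTPases rose (18 adjusted over the list alone; median 6.53), as did 24 of 25 type I interferon-stimulated genes (24 adjusted over the list alone; median 2.69). All 16 MHC class I genes rose (16 adjusted over the list alone; median 2.29). Signalling genes rose in 16 of 20, with Ifngr1† lower (16 and 1 adjusted over the list alone; median 2.54), and 11 of 18 chemokines and T-cell ligands rose (13 higher and 1 lower adjusted over the list alone; median 1.88). Gbp2 went from 20.4 ± 7.7 to 9087 ± 1118 CPM (log2 fold change 8.81 ± 0.23 SE, limma adjusted p = 5.0e-08). Cxcl9 again had 0 untreated reads and reached 709 ± 226 CPM, at least 5002-fold higher. Serpina3f, also without untreated reads, was at least 966-fold higher, and Iigp1, Gbp4, Serpina3g, Tgtp2 and Gbp5 rose by 7.58 to 9.66 log2 units. Stat1, Irf1, Cd274 and Cxcl10 rose by 3.71, 4.28, 3.87 and 7.45. Ptgs2, Tnf and Il1b rose by 3.10, 1.76 and 1.60. Nos2 rose to 18.2 ± 6.7 CPM, 197 times the untreated level with an interval of 54.2 to 1634 from 2 untreated reads. NF-kB inflammatory targets rose in 11 of 27 genes (15 higher and 1 lower adjusted over the list alone; camera adjusted p = 4.3e-11, adjusted p = 0.23 with an estimated correlation). Cx3cr1 fell from 76.8 ± 15 to 1.99 ± 1.0 CPM (-5.01), followed by Ypel2, Thbs1, the RNA sensor Tlr8, Itga6, Thbd, Ldlrad3 and the sphingosine receptor S1pr1 at -3.41 to -2.67. In all, 674 genes rose and 1336 fell, or 898 and 505 after median-of-ratios scaling (a shift of 0.24). Of the wild-type calls 609 rose and 988 fell in the knockout too, against 46.9 and 169 expected by chance. None moved in opposite directions (0). Without untreated knockout replicate 1 the total of 2010 became 1236, and a fit of the compared groups alone gave 748.

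**Figure D2:**
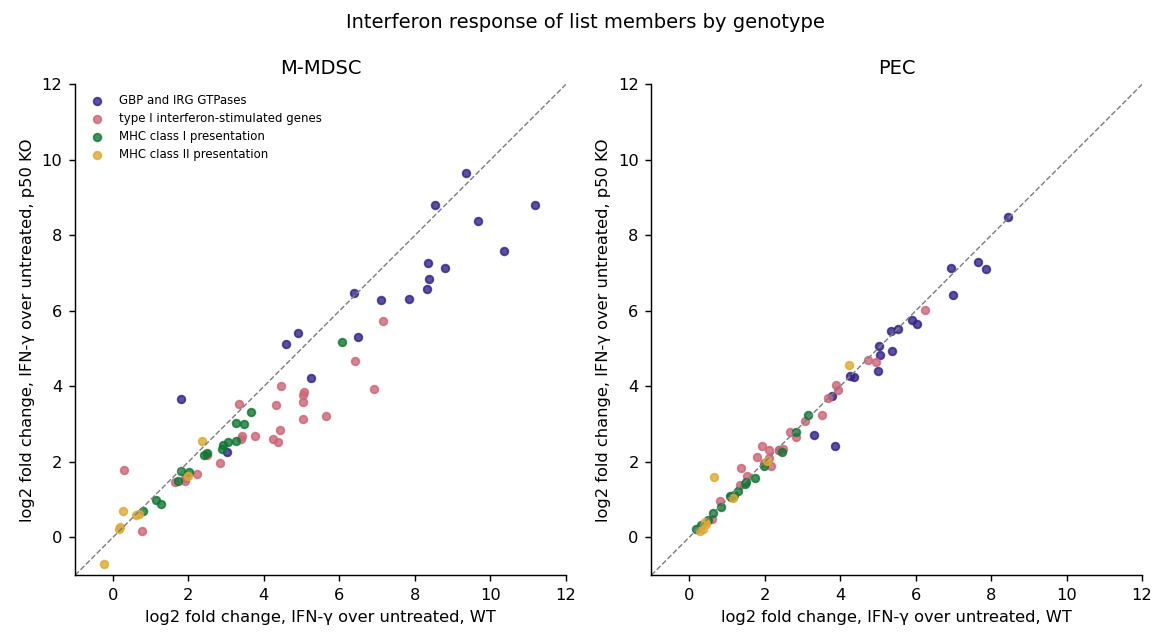
Log2 fold change with interferon-gamma over untreated in wild-type cells (horizontal) against knockout cells (vertical), in M-MDSC (left) and PEC (right), for genes of 4 lists by colour, with a dashed line at equal responses. In M-MDSC most type I interferon-stimulated genes lie below the line (median 4.24 in wild type and 2.69 in the knockout), and in PEC they lie along it (2.37 and 2.33).

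The difference between these responses was tested as an interaction, the knockout response minus the wild-type one. Rtp4, Oasl1 and Oas2, interferon-stimulated antiviral genes, rose less in knockout M-MDSC, with interactions of -2.98 ± 0.32, -2.42 ± 0.27 and -1.85 ± 0.21 log2 units (SE; limma adjusted p = 0.031 for each). Rtp4 was at 1.03 ± 0.43 CPM in the untreated and 180.3 ± 12 in the treated wild type, and at 15.2 ± 2.9 and 236 ± 9.2 in the knockout. These 3 were the interaction calls, with 0 genes higher, 181 at an unadjusted p under 0.05 and 20 calls by DESeq2. The 181 are fewer than the share of 0.05 of 11015 tested genes expected by chance. With 2 CPM added, or without the filter, 0 genes were called. The type I interferon-stimulated list had a negative interaction in 23 of 25 genes (3 lower over all genes, 14 lower adjusted over the list alone; median -0.88; camera adjusted p = 1.2e-27, adjusted p = 0.044 with an estimated correlation). The GBP and IRG list had a median of -1.05 (0 of 18 over all genes by limma, 1 higher and 11 lower adjusted over the list alone; camera adjusted p = 4.2e-11, adjusted p = 0.35 with an estimated correlation). NF-kB inflammatory targets had one of -0.52 (0 of 27, 1 lower adjusted over the list alone; camera adjusted p = 8.2e-08, adjusted p = 0.35 with an estimated correlation). The signalling, MHC class I, chemokine, macrophage differentiation and alternative activation lists also had negative interactions by camera (adjusted p of 3.1e-06, 1.5e-05, 0.0034, 0.027 and 0.011) and cell cycle genes a positive one (0.030), with 0 genes called over all and adjusted p of 0.25 to 0.49 with an estimated correlation. Nos2, Ptgs2 and Cxcl10 had interactions of -1.21, -1.38 and -1.82 that did not pass the test. The 3 calls became 0 to 4 with 1 library left out.

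Untreated knockout M-MDSC held more interferon-stimulated transcripts than untreated wild-type cells. Of the 25 type I interferon-stimulated genes 13 were higher (19 adjusted over the list alone), with a median log2 fold change of 1.61 (camera adjusted p = 1.1e-32, adjusted p = 0.032 with an estimated correlation). Rtp4 was at 15.2 ± 2.9 CPM against 1.03 ± 0.43 (log2 fold change 3.37 ± 0.23 SE, limma adjusted p = 0.00032). Oasl1 was at 9.89 ± 1.9 against 0.943 ± 0.019, Oas2 was higher by 2.12 log2 units, and Ifi27l2a was at 21.5 ± 3.0 against 4.09 ± 0.51. Of the GBP and IRG GTPases 7 of 18 were higher (11 adjusted over the list alone; median 1.02; camera adjusted p = 1.4e-14, adjusted p = 0.29 with an estimated correlation), with Gbp2 at 20.4 ± 7.7 against 3.80 ± 0.36 CPM and Gbp6 at least 18.3-fold higher. Irf9 and Irf7, which relay type I interferon signals, were the 2 of 20 signalling genes that were higher (5 adjusted over the list alone; camera adjusted p = 0.0026, adjusted p = 0.32 with an estimated correlation), while Stat1 was not called (136 ± 25 and 120.5 ± 1.9 CPM). MHC class I genes had a median of 0.36 (0 of 16 called by limma, 2 higher adjusted over the list alone; camera adjusted p = 0.00048, adjusted p = 0.45 with an estimated correlation). Ifi205, a DNA-binding interferon-inducible gene, Ly6i and the complement gene Cfb were higher by 2.52, 2.74 and 2.75 log2 units.

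Other single genes also differed in untreated knockout M-MDSC. Saa3, an acute-phase protein, was at 1029 ± 263 against 127 ± 52 CPM (3.05, adjusted p = 0.0026), and Lox, a collagen cross-linking enzyme, was higher by 3.53. Saa3 and Tnfaip3 were the 2 of 27 NF-kB inflammatory targets that were higher (5 adjusted over the list alone; camera adjusted p = 0.00063, adjusted p = 0.51 with an estimated correlation). Ptges, the terminal prostaglandin E2 synthase, was the 1 of 12 prostaglandin pathway genes that was higher (2 adjusted over the list alone), at 58.4 ± 8.6 against 21.5 ± 1.4 CPM. Il18 was the 1 higher of 18 chemokines and T-cell ligands (4 adjusted over the list alone; camera adjusted p = 0.043, adjusted p = 0.46 with an estimated correlation). Ly6c2, which encodes the Ly6C marker the labels give for these cells, was the 1 higher of 21 monocyte identity genes (1 adjusted over the list alone; log2 fold change 1.32). Stfa1, a cysteine protease inhibitor of granulocytes, was lower by 3.37, the zinc transporter gene Slc39a4 by 2.94, the endothelin receptor gene Ednrb by 1.90, Arhgap31 by 1.89 and Atg16l2 by 1.14. Emr1, the macrophage marker F4/80, was lower by 1.08 (1 lower of 24 macrophage differentiation genes, 1 adjusted over the list alone). Nos2, Arg1, Il10, Tnf, Cd274, Ccl2, Cxcl10 and Ptgs2 were not called, and none of the 22 effector genes was (0 by limma, also 0 adjusted over the list alone).

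Markers of other cells were mostly not called in untreated knockout M-MDSC. Of the 19 neutrophil and granulocyte markers 0 were called by limma, but 18 lay lower, with a median of -0.26 (0 adjusted over the list alone; camera adjusted p = 6.2e-05, adjusted p = 0.29 with an estimated correlation). B cell (3 tested), T cell (6), natural killer cell (7), dendritic cell (4), eosinophil and mast cell (3), erythroid and platelet (4) and sex-linked genes (4) had 0 calls, over all genes and adjusted over the list alone. In the fibroblast, tumour stroma and mesothelial list, Loxl2 was lower, with 0 reads in the knockout against 71 in the wild type (at least 19.9-fold; 1 of 3, with 1 higher and 1 lower adjusted over the list alone). Cell cycle genes had a median of -0.19 (0 of 24 by limma, 0 adjusted over the list alone; camera adjusted p = 0.00026, adjusted p = 0.29 with an estimated correlation). Alternative activation (1 higher of 12 adjusted over the list alone), resident peritoneal macrophage, stress and immediate early, sterol and lipid, glycolysis and hypoxia, and ribosomal protein genes had 0 calls over all genes by limma, 0 adjusted over the list alone in each but the first, and camera adjusted p of 0.12 or more.

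In all, 46 genes were higher and 9 lower in untreated knockout M-MDSC. Both libraries of knockout replicate 2 stood apart on the second principal component, which held 12.9% of the variance (-33.7 untreated and -29.5 treated, against 6.04 to 17.3 for the other 6 libraries). Without both there were 111 calls, without single libraries 16 to 60, with DESeq2 110, and with the compared groups alone 0 by limma.

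**Figure D3:**
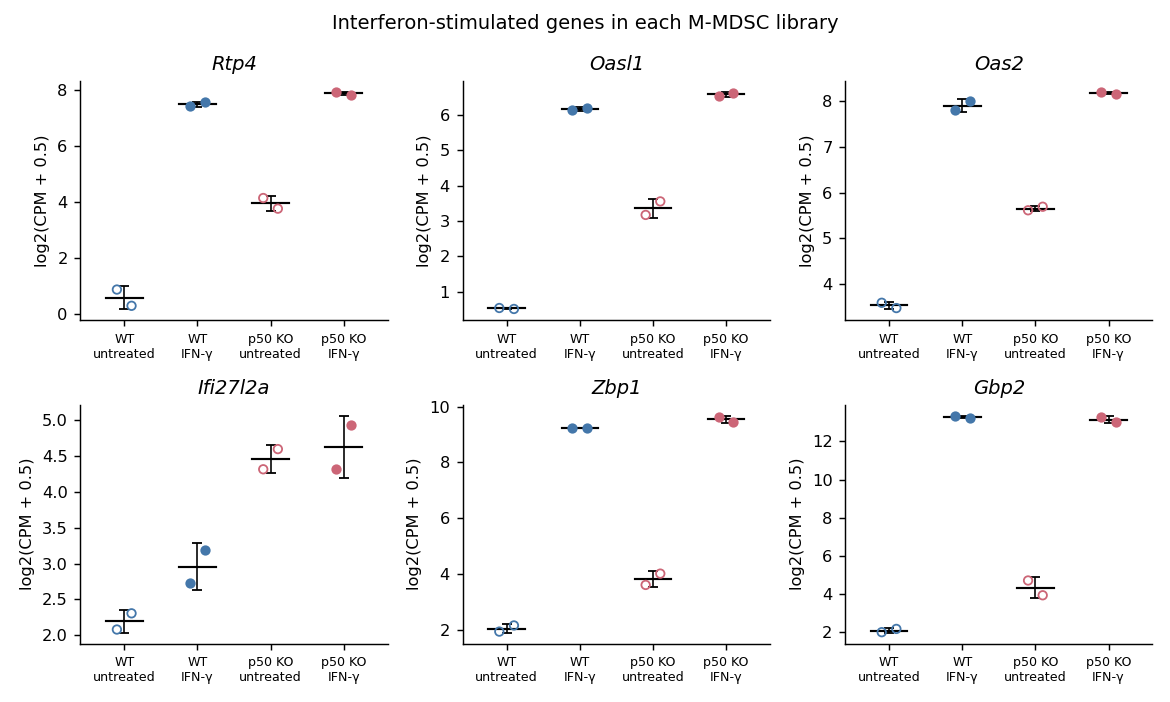
Levels of 6 interferon-stimulated genes in each M-MDSC library, as log2(CPM + 0.5), for the 4 groups, with single libraries as circles (open: untreated, filled: interferon-gamma) and bars for mean and SD (n = 2). For Rtp4 the untreated knockout (15.2 CPM) lies between the untreated (1.03) and the treated wild type (180.3).

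With interferon-gamma, 11 genes were higher and 8 lower in knockout M-MDSC. Of 11015 tested genes 752 had an unadjusted p under 0.05, against 721 in untreated cells and a share of 0.05 expected by chance. Saa3 (1801 ± 207 against 262 ± 72 CPM, 2.80), Lox (3.25) and Ptges (1.66) were again higher, with Pgm2l1, Oas1g, Osbpl3 and the cytokine gene Il18 (2.26, 1.89, 1.80 and 1.38). Stfa1, the small GTPase gene Rnd1, Emr1, the transcription factor gene Pou2f2, Atg16l2, Nfkb1 and Siglece were lower, by 2.82 to 0.91. The calls shared with the untreated comparison were 7 higher and 5 lower. Nos2 was at 18.2 ± 6.7 CPM in the knockout and 56.6 ± 1.6 in the wild type, which did not pass the test (-1.66, limma adjusted p = 0.087), and Ptgs2 at 7.21 ± 2.1 and 21.3 ± 4.0 (-1.51, adjusted p = 0.19). Type I interferon-stimulated genes had 0 of 25 calls (3 higher adjusted over the list alone; limma) and a median of 0.39 (camera adjusted p = 4.6e-06, adjusted p = 0.42 with an estimated correlation), against 1.61 in untreated cells. Macrophage differentiation genes had a median of -0.28 (1 lower of 24, Emr1; 2 lower adjusted over the list alone; camera adjusted p = 0.0014, adjusted p = 0.60 with an estimated correlation), and the NF-kB and IkB family one of -0.27 (1 lower of 14, Nfkb1; 2 lower adjusted over the list alone; camera adjusted p = 0.0014, adjusted p = 0.52 with an estimated correlation). The GBP and IRG list had a median of 0.21 (0 of 18 by limma, 1 higher adjusted over the list alone; camera adjusted p = 0.018, adjusted p = 0.70 with an estimated correlation) and the effectors one of -0.19 (0 of 22, 1 lower adjusted over the list alone; camera adjusted p = 0.018, adjusted p = 0.42 with an estimated correlation). Natural killer cell markers had a median of 0.55 (0 of 7, 0 adjusted over the list alone; camera adjusted p = 0.047, adjusted p = 0.70 with an estimated correlation). Neutrophil markers had a median of -0.17 (0 of 19 by limma and adjusted over the list alone; camera adjusted p = 0.0091, adjusted p = 0.60 with an estimated correlation). The 19 calls became 1 without either wild-type treated library, 232 without both libraries of knockout replicate 2, and 99 with DESeq2.

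In wild-type PEC, interferon-gamma raised the 5 lists of interferon genes as well, by camera with the preset correlation (adjusted p of 0.091 to 0.16 with an estimated one). All 18 GBP and IRG GTPases (18 adjusted over the list alone; median 5.36), all 25 type I interferon-stimulated genes (25 adjusted over the list alone; median 2.37) and all 16 MHC class I genes (16 adjusted over the list alone; median 1.24) rose. So did 17 of 20 signalling genes (17 adjusted over the list alone) and 14 of 16 chemokines and T-cell ligands (14 adjusted over the list alone). Ifngr1† and Ifngr2† of the former and Cd80† of the latter fell. Serpina3g, Iigp1, Cxcl9, Gbp4, Serpina3f, Gbp5 and Gbp2 rose by at least 6.99 log2 units, and Cxcl9 reached 579.9 ± 68 CPM from 1.43 ± 0.062. Cd274 rose from 166 ± 12 to 3204 ± 236 CPM, Stat1 from 134 ± 2.4 to 779 ± 38 and Ciita, the master regulator of MHC class II genes, from 20.2 ± 5.3 to 381 ± 17 (4.23, adjusted p = 7.1e-08). MHC class II presentation rose in 3 of 8 genes, Ciita, H2-DMa and H2-DMb1 (3 adjusted over the list alone; camera adjusted p = 0.00084, adjusted p = 0.36 with an estimated correlation). Nos2 reached 8.71 ± 1.7 CPM, 449 times the untreated level with an interval of 80.1 to 17765 from 1 untreated read. Ptgs2 rose from 1.37 ± 0.18 to 56.0 ± 14 CPM, Tnf by 2.07 log2 units, Ccl2 by 1.66, Cxcl10 by 6.68 and Irf1 by 4.54, and Arg1 did not pass the test (30.0 ± 14 and 52.5 ± 29 CPM). Among the genes ranked by the rule for named genes, S1pr1, which guides cell exit from tissue, fell most (log2 fold change -4.60). It was followed by Ypel2, Cx3cr1, Nuak1, Nav2, the prokineticin receptor gene Prokr1, Tacc2 and Gpr183 at -3.82 to -3.42.

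Lists of other functions split in wild-type PEC. NF-kB inflammatory targets rose in 13 of 26 genes and fell in 7 (13 and 7 adjusted over the list alone; camera adjusted p = 0.0037, adjusted p = 0.22 with an estimated correlation), with Icam1 and Sod2 higher and Ccl3, a monocyte chemokine, lower (-1.74). Suppressor effectors had 9 higher and 5 lower of 20 (9 and 5 adjusted over the list alone; camera adjusted p = 0.0018, adjusted p = 0.16 with an estimated correlation). Prostaglandin pathway genes had 5 higher and 6 lower of 13 (5 and 6 adjusted over the list alone) and alternative activation genes 7 higher and 1 lower, Irf4†, of 12 (7 and 1 adjusted over the list alone; camera adjusted p = 0.00084, adjusted p = 0.091 with an estimated correlation). Of 20 cell cycle genes 11 fell, among them Mcm2, Mcm3 and Mcm4 of the replication helicase (10 lower adjusted over the list alone; camera adjusted p = 0.18). The NF-kB and IkB family split into 8 higher and 4 lower of 14 (8 and 4 adjusted over the list alone; camera adjusted p = 0.013, adjusted p = 0.40 with an estimated correlation), and dendritic cell markers rose in 4 of 5, Clec9a, Kmo, Batf3 and Clec10a (4 adjusted over the list alone; camera adjusted p = 0.0013, adjusted p = 0.22 with an estimated correlation). Ch25h, which makes 25-hydroxycholesterol, rose by 4.85, and the cholesterol exporter gene Abca1 fell by 2.33. Of 22 ribosomal protein genes 1 rose, Rpl3, and 10 fell (1 and 8 adjusted over the list alone), and as a list they lay lower as deposited and higher after median-of-ratios scaling (camera adjusted p = 0.65 and 0.11). Over 11242 genes 1997 rose and 5813 fell as deposited, against 3381 and 3019 after median-of-ratios scaling (a shift of 0.23), and 729 rose and 779 fell by 2-fold or more. None of the list calls in PEC was kept with an estimated correlation (0 lists, against 41 with the preset one).

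Knockout PEC responded to interferon-gamma in the same lists. All 18 GBP and IRG GTPases (18 adjusted over the list alone), 25 type I interferon-stimulated genes (25 adjusted over the list alone) and 16 MHC class I genes (16 adjusted over the list alone) rose again, with medians of 5.26, 2.33 and 1.16 (estimated-correlation adjusted p of 0.088, 0.13 and 0.088). Iigp1, Serpina3g, Serpina3f, Gbp5, Tgtp2, Gbp4, Socs1, a feedback inhibitor of interferon signalling, and Cxcl9 rose by 6.98 to 8.50. Tnf, Ccl2, Cxcl10, Ptgs2, Stat1, Irf1 and Cd274 rose by 2.63, 2.54, 6.15, 4.22, 2.36, 4.92 and 4.47. S1pr1, Nuak1, Tcp11l2, Ypel2, Prokr1, the sphingomyelinase gene Smpd3 and the complement receptor gene C5ar1 fell by 4.09 to 3.30. MHC class II genes rose in 4 of 8, Ciita, H2-DMa, H2-DMb1 and H2-DMb2 (4 adjusted over the list alone; camera adjusted p = 0.00059, adjusted p = 0.32 with an estimated correlation). Nos2 was at 0.435 ± 0.15 CPM with interferon-gamma (log2 fold change 0.79), 11.2 times the untreated level with an interval of 2.77 to 97.4 from 2 untreated reads. Over all genes 1964 rose and 5938 fell (3383 and 3071 after median-of-ratios scaling), of which 1789 and 5214 were shared with the wild type and 6 moved in opposite directions.

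Untreated knockout PEC held less MHC class II transcript than wild-type PEC. Of the 8 class II genes 7 were lower (7 adjusted over the list alone), with a median log2 fold change of -1.04 (camera adjusted p = 0.00020, adjusted p = 0.44 with an estimated correlation). H2-Aa was at 121 ± 29 against 322 ± 65 CPM (-1.42 ± 0.21 SE, limma adjusted p = 0.0048), Cd74, the class II invariant chain, at 339.8 ± 92 against 762 ± 116, H2-Eb1 was lower by 1.21 and Ciita by 0.98. B cell markers, of which 4 were tested, had 3 lower (Ms4a1, Cd79b, Cd19) and 1 higher (Cd22, by 0.37), with the same counts adjusted over the list alone. Ms4a1 and Cd79b were at 0.117 ± 0.056 and 0.724 ± 0.026 CPM against 1.67 ± 0.76 and 1.86 ± 0.66. The NF-kB and IkB family was lower in 6 of 14 genes (8 adjusted over the list alone; median -0.30; camera adjusted p = 0.00015, adjusted p = 0.44 with an estimated correlation), with Nfkbie, an inhibitor of NF-kB, at -0.98 and Relb at -0.83 after Nfkb1. NF-kB inflammatory targets were lower in 8 of 26 genes and higher in 2 (16 and 4 adjusted over the list alone; camera adjusted p = 0.020, adjusted p = 0.44 with an estimated correlation). The neutrophil chemokine gene Cxcl3 was lower by 1.80 log2 units and the cytokine gene Il1a higher by 1.31.

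Other genes of untreated knockout PEC differed on their own. Hal, a histidine-degrading enzyme, was at 144 ± 25 CPM in the untreated knockout and 4.00 ± 0.52 in the wild type (5.00 ± 0.18 SE, limma adjusted p = 1.2e-06). Htra1, Tns1, Mcoln3, Adam19, Cd24a and Sema4b were higher by 1.09 to 1.57. Arg1 was at 4.05 ± 0.75 against 30.0 ± 14 CPM (-2.67, adjusted p = 0.0036), and Cx3cr1, Ebi3, a subunit of interleukin 27, Ceacam19, Slc9a3r2, Wdfy1 and Clec4n, a C-type lectin, were lower by 2.19 to 1.80. Effector genes were lower in 5 of 20, Slc7a2, Ncf4, Arg1, Hmox1 and Ass1†, and higher in 1, Entpd1† (6 and 1 adjusted over the list alone; camera adjusted p = 0.052). Type I interferon-stimulated genes were higher in 5 of 25, Ifit2, Rsad2, Oas3, Cmpk2 and Ifi44† (7 adjusted over the list alone; median 0.15; camera adjusted p = 3.2e-05, adjusted p = 0.53 with an estimated correlation), with Rsad2 at 0.81. Macrophage differentiation genes were higher in 5 of 26, Apoe, Spp1, Fcgr4, Fabp5† and Mrc1†, and lower in Emr1 (9 and 2 adjusted over the list alone; camera adjusted p = 0.00040, adjusted p = 0.39 with an estimated correlation). Cell cycle genes were lower in 3 of 20, Top2a, Mki67 and Mcm5 (7 adjusted over the list alone; camera adjusted p = 9.3e-05, adjusted p = 0.44 with an estimated correlation). Resident peritoneal macrophage genes were lower in 1 of 11, Timd4 (1 adjusted over the list alone; camera adjusted p = 0.043, adjusted p = 0.53 with an estimated correlation). Sterol and lipid genes were higher in 1 of 16, Abcg1 (1 adjusted over the list alone; camera adjusted p = 3.2e-05, adjusted p = 0.53 with an estimated correlation). Ribosomal protein genes were lower in 2 of 22, Rplp0 and Rpl18 (8 adjusted over the list alone; camera adjusted p = 0.0024, adjusted p = 0.39 with an estimated correlation). The neutrophil list, with 5 genes tested, was lower in the protease genes Mmp9 and Mmp8 (3 lower adjusted over the list alone). Cxcl9 was lower (-0.86, adjusted p = 0.017), Stat1, Irf1, Cd274, Tnf, Ccl2, Cxcl10 and Ptgs2 were not called, and Nos2 was near its floor in both genotypes. The totals were 287 higher and 519 lower, or 486 and 288 after median-of-ratios scaling, with 24 and 65 of 2-fold or more. Without 1 library at a time the 806 calls became 227 to 568.

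**Figure D4:**
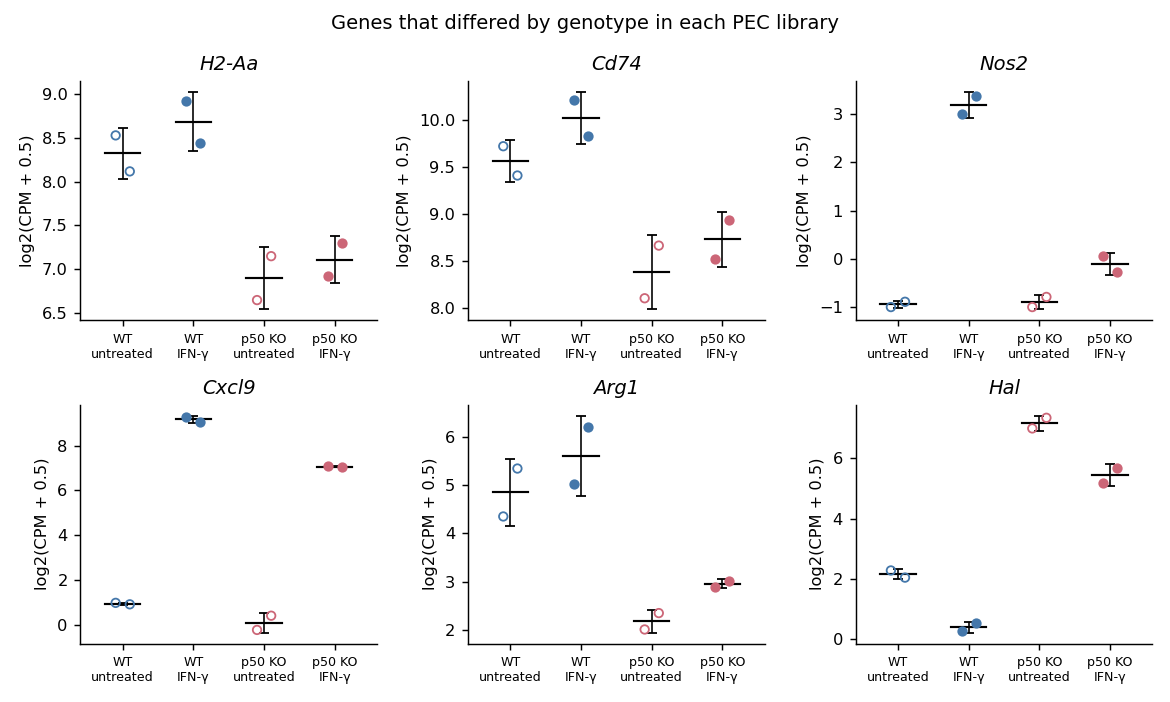
Levels of 6 genes in each PEC library, as log2(CPM + 0.5), for the 4 groups, with single libraries as circles (open: untreated, filled: interferon-gamma) and bars for mean and SD (n = 2). H2-Aa, Cd74 and Arg1 lie lower in the knockout in both treatments and Hal higher, while Nos2 differs with interferon-gamma and Cxcl9 lies lower in the knockout in both treatments (with interferon-gamma at 134 CPM against 579.9 in the wild type).

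With interferon-gamma the PEC genotypes differed in 750 higher and 1450 lower genes (1187 and 734 after median-of-ratios scaling), 40 and 97 of them by 2-fold or more. Nos2 was at 0.435 ± 0.15 CPM in the knockout and 8.71 ± 1.7 in the wild type (-3.30 ± 0.21 SE, limma adjusted p = 3.1e-05), and Cxcl9 at 134 ± 1.2 and 579.9 ± 68 (-2.11, adjusted p = 9.5e-05). Ptgs2 (-1.33), Cxcl10 (-0.70) and Stat1 (-0.49) were lower, while Irf1, Cd274, Tnf and Ccl2 were not called. Arg1 (-2.66), Ebi3, Pcdh7, Ceacam19, Camk2b and Wdfy1 were lower by at least 1.91 log2 units, and Hal (5.03), Tns1, Rab15, Htra1, Il1a, Mcoln3, Pydc3 and the T-cell ligand gene Cd276 higher by at least 1.43. MHC class II genes were lower in 7 of 8 (7 adjusted over the list alone; median -0.88; camera adjusted p = 0.011, adjusted p = 0.71 with an estimated correlation), with H2-Aa at 139 ± 25 against 416 ± 97 CPM, and B cell markers again in 3 of 4 with Cd22 higher (3 lower and 1 higher adjusted over the list alone). The effectors were lower in 7 of 20 (7 adjusted over the list alone; camera adjusted p = 0.020, adjusted p = 0.71 with an estimated correlation). NF-kB inflammatory targets split into 5 higher and 9 lower of 26 (5 and 10 adjusted over the list alone; camera adjusted p = 0.57), Ccl3 and Ccl4, chemokines, being higher (0.69 and 0.94). Type I interferon-stimulated genes were higher in 5 of 25, Rsad2, Ifit2, Cmpk2, Oas2 and Isg20† (5 adjusted over the list alone; median 0.15; camera adjusted p = 0.00034, adjusted p = 0.71 with an estimated correlation). The NF-kB and IkB family (0 higher and 6 lower of 14), macrophage differentiation (9 and 2 of 26), cell cycle (0 and 7 of 20) and sterol lists (1 and 1 of 16) kept the directions seen in untreated cells (camera adjusted p of 0.0059, 0.013, 0.0032 and 0.031, each 0.71 with an estimated correlation). Adjusted over the list alone, the counts were 0 and 6, 11 and 6, 0 and 10, and 1 and 1. The calls shared with the untreated comparison were 230 higher and 362 lower, with 5 in opposite directions. As an interaction, 7 genes passed, of 965 at an unadjusted p under 0.05. Nos2 (-3.35 ± 0.29 SE, limma adjusted p = 0.0046), the fatty acid activating enzyme gene Acsl1 (-1.14), Rab43, Gatm and Nfatc2 rose less or fell more in the knockout, and Wdhd1 (0.92) and Rnd3 (0.83) the reverse. As lists, the GBP and IRG GTPases had a negative interaction (0 of 18 by limma, 6 lower adjusted over the list alone; camera adjusted p = 0.0029, adjusted p = 0.98 with an estimated correlation) and NF-kB inflammatory targets a positive one (0 of 26, 6 higher adjusted over the list alone; camera adjusted p = 0.0013, adjusted p = 0.88 with an estimated correlation). The Cxcl9 interaction of -1.25 did not pass (adjusted p = 0.11). The 2200 genotype calls with interferon-gamma became 939 to 1420 without 1 library at a time, and the 7 interaction calls 2 to 7, or 45 with DESeq2.

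The 2 cell types were compared by their calls, since their tables were normalized separately. Of 729 genes that rose with interferon-gamma in wild-type M-MDSC and were tested in both, 626 rose in PEC, against 131 expected by chance (odds ratio 41.1, 95% interval 33.0 to 51.6). Of 1301 that fell 1121 fell in PEC, against 680 expected by chance (odds ratio 6.90, Fisher's exact p = 6.8e-167). The expected number is large because 5401 of the 10326 genes were called lower in PEC with the deposited scaling. At 2-fold or more, 250 of 534 fell in both, against 33.6 expected (odds ratio 20.7). In the knockout 557 of 639 rose in both (113 expected, odds ratio 45.2) and 1105 of 1262 fell in both (678 expected, odds ratio 7.33, exact p = 1.2e-164). For the knockout against the wild type, untreated, 7 of 43 genes higher in M-MDSC were higher in PEC (1.03 expected, odds ratio 8.13, 3.02 to 18.8, Fisher's exact p = 6.4e-05) and 4 of 8 lower genes, with Nfkb1 among them, were lower in both (0.364 expected, exact p = 0.00026). With interferon-gamma the overlaps of 2 of 8 higher (exact p = 0.091) and 2 of 7 lower genes, again with Nfkb1 among them (exact p = 0.23), did not pass. With a replicate block, which takes up differences shared by same-numbered libraries, both passed, at 13 of 55 (exact p = 0.00033) and 14 of 26 (exact p = 6.0e-06).

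STAT1 ChIP-seq of PEC gave few peaks before interferon-gamma in the wild type, more in the untreated knockout, and many after treatment in both. The deposited lists, 1 library each and so without a replicate check, held 2103 peaks in untreated and 45035 in treated wild-type PEC, and 10190 and 39953 in the knockout. They came from 18.2, 20.5, 18.8 and 23.2 M filtered tags against 1 shared input. The lists covered 2.51, 52.9, 14.2 and 53.2 Mb and held 0.769, 29.0, 3.88 and 25.2% of the tags, at a mean of 55.6, 112, 51.6 and 110 tags per kb of peak. With the authors' score at 100 or more, the numbers were 531, 32063, 3780 and 28220. Of the treated wild-type peaks 80.7% shared at least 1 bp with a treated knockout peak (95% Wilson interval 80.3 to 81.0%) and 89.2% the other way, against 9.24 and 10.4% when the peaks were moved by 100 kb. In the top-scoring quintile of the treated wild-type peaks that share was 99.9% and in the lowest quintile 43.6%. Of the untreated wild-type peaks 88.0% overlapped an untreated knockout peak, and 18.2% of untreated knockout peaks an untreated wild-type one, a contrast that the length of the lists sets. With the 2103 top-scoring peaks of each list the shares were 53.7 and 53.5%. Of the untreated knockout peaks 94.3% overlapped a treated wild-type peak (10.4% when moved), or 14.4% between the 2103 top-scoring peaks of both. Merged over the 4 lists there were 48126 regions, 25449 of them (52.9%) in both treated lists alone, 7374 (15.3%) in those and the untreated knockout, 1797 in all 4, 8362 in the treated wild type alone and 4064 in the treated knockout alone.

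The order of the strongest peaks is uncertain, since peaks of all 4 lists are tied at a score of 3100. A score above 3100 need not mark a stronger peak. In the untreated wild type a peak at 3138 held 318 tags at 96.3-fold, and another at 3100 held 741 tags at 117-fold. Fold enrichment reached 287 in the treated wild-type list and 246 in the treated knockout list, above that of their highest-scoring peaks. Among the top-scoring untreated wild-type peaks were those on chromosome 8 at 23969347 to 23970235 (mm9, score 3138), chromosome 11 at 100800320 to 100801686 and chromosome Y at 2779416 to 2786007 (both 3100). Their fold enrichments by the authors' caller were 96.3, 117 and 113, and all were listed in all 4 libraries. The treated wild-type peak with the highest score, on chromosome 7 at 148233241 to 148235329 (53.0-fold), overlapped a treated knockout peak of 37.1-fold and no untreated peak. Of the treated knockout peaks, 2 were tied at a score of 3233, on chromosome 1 at 173755589 to 173758763 (57.5-fold) and on chromosome 6 at 34811754 to 34815013 (53.4-fold). The former overlapped peaks of 77.7-fold in the treated wild type, 11.3-fold in the untreated knockout and 5.63-fold in the untreated wild type. No mm9 gene annotation was used here, so the genes at these places are not given.

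**Figure D5:**
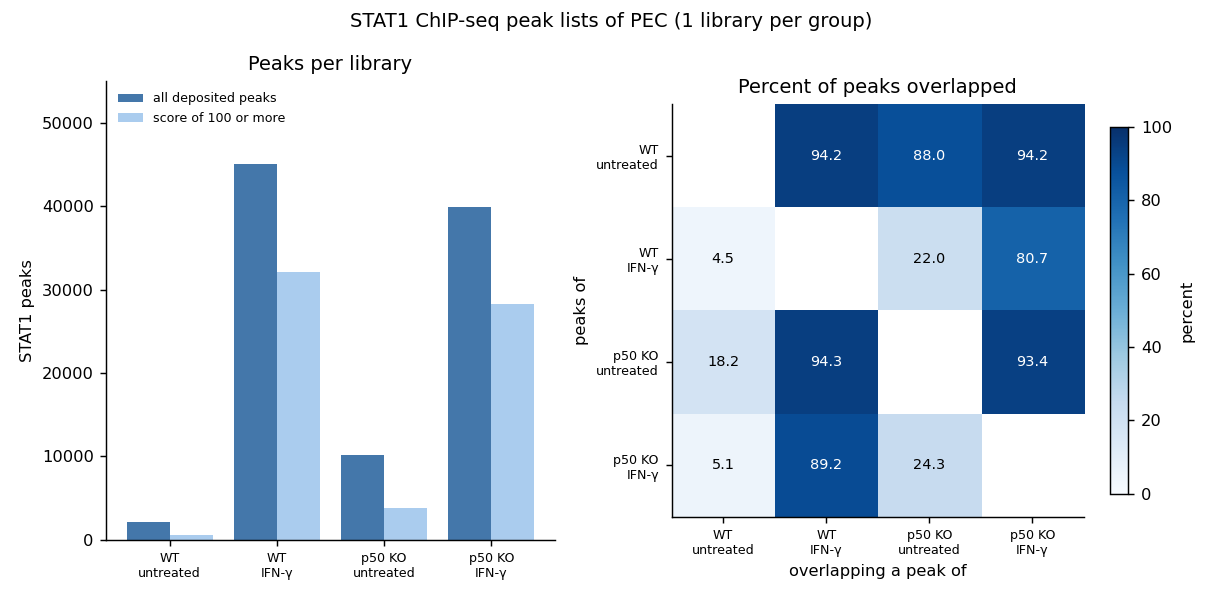
STAT1 peaks of PEC, as the number per library, all deposited and with a score of 100 or more (left), and as the percent of the peaks of each list (vertical) that overlap a peak of another list (horizontal) by at least 1 bp (right). The untreated knockout list (10190 peaks) is longer than the untreated wild-type one (2103), and 94.3% of it overlaps the treated wild-type list.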

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

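Tests of technical explanations in this part were chosen after the results were seen. A test of the difference between genotypes in the interferon-gamma response flagged 3 genes in M-MDSC, with interactions of -2.98 for Rtp4, -2.42 for Oasl1 and -1.85 for Oas2 (log2 units, knockout minus wild type). The untreated levels of these interferon-stimulated genes were also higher in the knockout, so the pattern weighed here is the higher level of interferon-stimulated genes in untreated knockout M-MDSC.

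Neither 1 knockout library nor carry-over of treated RNA accounts for the whole of that pattern, while a shift in cell shares could not be decided. The genotype, the biological explanation given by the design, may account for the pattern. It was not tested apart from the animals and preparations it came with. If 1 knockout library carried the difference, the list median would fall without it, but it was 1.33 without untreated replicate 2 and 1.74 without replicate 1, with 12 members higher each time. If treated RNA had been carried over, every induced gene would be raised by 1 share of its treated level, but 22 genes outside the list that were induced by 6 log2 units or more in the wild type had a median excess of 0.377% of the treated level (quartiles 0.0870 and 0.693%), against 7.05% for the list (quartiles 5.61 and 11.1%) and 3.09% for its 3 members induced as strongly. A shift from neutrophil to monocyte cells could add to the difference, although Ly6G positive cells were separated off in the isolation. The monocyte identity list had a median of 0.35, Ly6c2 was higher by 1.32 and 18 of 19 neutrophil markers lay lower (median -0.26). Not all values went that way. The lower quartile of the monocyte list was -0.196, and the macrophage marker Emr1 was at -1.08. The macrophage differentiation list that holds Emr1 had a median of 0.112. As the whole of the difference, the shift would raise genes of monocytes alone by about the 1.61 of the interferon-stimulated list. The upper quartile of the monocyte list was 0.587, but that list also holds genes that neutrophils express. Such genes keep the list low under a shift of any size, so this test cannot decide. Exposure to interferon in the animal or in culture before collection could not be told apart from an effect of p50 in the cells.

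The same test flagged 7 genes in PEC. Nos2 had an interaction of -3.35, Acsl1 of -1.14, Rab43 of -0.88, Gatm of -0.74 and Nfatc2 of -0.67, and Rnd3 and Wdhd1 had interactions of 0.83 and 0.92. Among the genes that the rule for named genes gives, opposite directions in every library of the 2 cell types flagged 3 further ones, and these differences were not tested. Ccl3 with interferon-gamma in the wild type was at 0.64 in M-MDSC and -1.74 in PEC, Osbpl3 in the treated knockout against the wild type at 1.80 in M-MDSC and -1.13 in PEC, and Lox in the untreated knockout against the wild type at 3.53 in M-MDSC and -0.67 in PEC.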

How the results depend on the processing

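The alternatives were chosen before the data were examined, except the fit without both libraries of knockout M-MDSC replicate 2. Each result for a named gene (208 in M-MDSC and 269 in PEC) was compared with its main value once per alternative fit that held it. Of these comparisons 3436 in M-MDSC and 4087 in PEC kept their side of the threshold, and called values among them kept their direction. A further 247 and 228 lost the call, 48 and 37 gained it, and 52 in M-MDSC and 0 in PEC reversed. The grouping by the treatment entry gave all 52 reversals and 84 of the losses in M-MDSC. Groups of 2 leave little to estimate the spread, depth sets the floor of 3 reads at 0.199 to 0.316 CPM in M-MDSC and 0.108 to 0.123 CPM in PEC, and fits without 1 library assume that the lone one varies like the other groups. Peaks near interferon-responsive genes, planned for an mm9 annotation, were not run, with their alternatives. The cause of the changes below was not tested, except where fewer libraries or a stricter threshold lower a count by construction.

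In M-MDSC, calls with interferon-gamma in the wild type became 1167 at 2-fold or more, 4290 with the compared groups alone and 4292 without knockout replicate 2, and in the knockout 1072 and 748 in the first and second of these. Untreated genotype calls became 110 with DESeq2, 0 with the compared groups alone and 111 without knockout replicate 2, and treated ones 99, 30 and 232. Interaction calls became 5 with 0.1 CPM added, 0 with 2 CPM added, 0 without the filter, 20 with DESeq2 and 10 without knockout replicate 2. With 1 library left out, calls were 703 to 1054 for interferon-gamma in the wild type (each of untreated and treated wild-type replicates 1 and 2), 1236 to 1933 in the knockout (1236 without untreated knockout replicate 1), 16 to 60 for the untreated genotypes (26 without untreated wild-type replicate 1 and 16 without replicate 2), 1 to 15 for the treated ones (1 without either treated wild-type replicate) and 0 to 4 for the interaction (1 without untreated wild-type replicate 1, 0 without its replicate 2, either treated wild-type replicate or treated knockout replicate 1).

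In PEC, calls with interferon-gamma became 1508 and 1467 (wild type and knockout) at 2-fold or more and 5171 and 5163 with DESeq2. Untreated genotype calls became 462 without the filter and 89 at 2-fold or more, and treated ones 137 at 2-fold or more and 1363 with DESeq2. Interaction calls became 2 with 0.1 CPM added, 27 with 2 CPM added, 2 without the filter, 13 with quantile scaling, 2 at 2-fold or more, 17 with robust moderation and 45 with DESeq2. With 1 library left out, calls were 6857 to 7120 and 6813 to 7056 for interferon-gamma, 227 to 568 for the untreated genotypes (305 without untreated wild-type replicate 1, 227 without untreated knockout replicate 1, 343 without its replicate 2), 939 to 1420 for the treated ones (954 and 1411 without treated wild-type replicates 1 and 2, 1420 and 939 without treated knockout replicates 1 and 2) and 2 to 7 for the interaction (2 without untreated wild-type replicate 1, 3 and 4 without treated wild-type replicates 1 and 2, 3 and 2 without untreated knockout replicates 1 and 2, 4 without treated knockout replicate 1 or 2).

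The labels do not state that equal replicate numbers tie libraries together, but some of their values go together, with correlations of the same-numbered deviations of 0.0976 to 0.679 in M-MDSC (0.679 for the knockout libraries, untreated and treated) and -0.0104 to 0.379 in PEC. With a replicate block, M-MDSC genotype calls became 121 untreated and 91 treated and interaction calls 8, PEC interaction calls 38, and the odds ratio of the treated genotype overlap between cell types 3.57 (higher) and 6.47 (lower), both then past the test. List calls with the block were 45 in M-MDSC and 43 in PEC.

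List calls fell from 45 to 12 with an estimated correlation and to 18 with fry in M-MDSC, and from 41 to 0 with an estimated correlation in PEC, where fry gave 50. At 2-fold or more the odds ratio of the untreated genotype overlap was 0 for higher genes. There 0.0569 shared genes were expected by chance, so that it shows no change of side. That of the treated overlap was 27.6 for lower genes. It rests on 1 shared gene of 6, the knocked-out gene Nfkb1 itself, so it does not speak for a shared effect on other genes. Peaks with a score of 100 or more numbered 531 (untreated wild type) and 3780 (untreated knockout). Overlap with that score, with 50% reciprocal overlap and with the 2103 top peaks of each list was 81.5, 75.5 and 87.3% for treated wild-type in treated knockout peaks, 91.0, 85.1 and 87.0% the other way, 12.7, 16.5 and 53.5% for untreated knockout in untreated wild-type peaks, 89.8, 80.1 and 53.7% the other way, 97.3, 84.7 and 14.4% for untreated knockout in treated wild-type peaks, and 1.61, 3.63 and 15.0% for treated in untreated wild-type peaks.

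Groups taken from the treatment entry instead of the titles gave 0 calls for interferon-gamma in each genotype, 2 and 1 for the untreated and treated genotypes and 0 for the interaction in M-MDSC, and reversed 52 values. In the wild-type contrast these were Batf2 -0.58, Cd274 -0.046, Cxcl9 -0.39, Entpd1 -0.013, Fcgr1 -0.11, Gbp5 -0.38, Gbp6 -0.25, Gpr183 0.66, Icam1 -0.23, Ifi47 -0.11, Igtp -0.11, Iigp1 -0.42, Il1b -0.13, Irf1 -0.12, Irf8 -0.31, Nlrc5 -0.27, Parp14 -0.074, Pdcd4 0.063, Pde4b -0.16, Ptger2 0.027, Ptgs2 -0.20, Rtp4 -0.22, Slc7a2 -0.49, Stat1 -0.040, Tgtp2 -0.0043, Tnfaip2 -0.025 and Tnfaip3 -0.18. In the knockout contrast they were Cd274 -0.23, Cxcl9 -0.33, Entpd1 -0.58, F13a1 0.057, Gbp2 -0.51, Gbp4 -0.0013, Gbp5 -0.51, Gpr141 -0.36, Herc6 -0.41, Igtp -0.32, Il18bp -0.15, Irf1 -0.066, Ldlrad3 0.047, Nlrc5 -0.22, Oasl2 -0.55, Pde4b -0.18, Ptger2 0.15, Ptges -0.00048, Rtp4 -0.23, S1pr1 0.22, Serpina3g -0.19, Stat1 -0.37, Tgtp2 -0.60 and Tnfaip3 -0.053, and in the interaction Oasl1 0.22. This grouping puts 1 treated and 1 untreated library, by title, in each group. On the first principal component, with 68.7% of the variance, M-MDSC libraries titled untreated lay at -49.1 to -34.9. Those titled treated lay at 38.2 to 45.1. Groups by the treatment entry would each hold libraries from both sides, which argues against that entry for these libraries.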

Other observations

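Tests of technical explanations in this part were chosen after the results were seen, except the comparison of STAT1 peaks with moved peaks, whose prediction was written before. Some genes answered interferon-gamma in opposite directions in the cell types, which was not tested as a difference because the tables were normalized separately. In the wild type 83 genes were called in opposite directions in M-MDSC and PEC, in the knockout 72, and 35 in both genotypes with no overlap between libraries. Many more genes were called in the same direction, 626 higher and 1121 lower in the wild type and 557 and 1105 in the knockout. All these counts rest on the deposited scaling. Median-of-ratios scaling moved the median PEC gene up by 0.23 log2 units in the wild-type response and by 0.24 in the knockout one. Small falls in PEC, such as Cybasc3† at -0.19 and -0.15, lie within that shift. Sema7a, a membrane-anchored semaphorin, was at -2.45 and -2.30 log2 units in wild-type and knockout M-MDSC and at 1.62 and 1.81 in PEC. Serpinb1a, an inhibitor of neutrophil proteases, was at -1.25 and -1.19 against 1.71 and 1.82, and the myosin gene Myo1d at -1.28 and -1.19 against 1.53 and 1.43. Kcnj2, a potassium channel, went the other way, at 1.18 and 1.46 in M-MDSC and -1.95 and -2.12 in PEC. These 4 genes were chosen after their values were seen.

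Stfa1 and the gene model BC117090, both of the stefin A gene family, moved in opposite directions in knockout M-MDSC. BC117090 was at 34.6 ± 4.0 CPM against 1.33 ± 0.56 untreated and Stfa1 at 1.66 ± 0.68 against 21.4 ± 2.7. Copies of this family are similar, so reads can be shared between them, and these genes were chosen after their values were seen.

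The lower MHC class II level of knockout PEC may reflect the make-up of the cells rather than their regulation. Fewer B cells cannot be told apart from it with so few reads and libraries. The class II genes moved against 3 B cell markers between replicates in 2 of 4 groups, both wild-type (log2 of replicate 2 over 1 of -0.361 and -0.436 against 0.586 and 0.964). In the knockout groups class II moved by 0.422 and 0.331, and the B cell markers, at 24 and 30 reads untreated and 21 and 20 treated, by no more than counting error (ratios of 1.25, 0.708 to 2.24, and 0.971, 0.4995 to 1.88). The wild-type ratios were 1.78 (1.37 to 2.33) and 1.75 (1.27 to 2.42), and all these intervals cover counting error alone, not the spread between libraries. Cd22, which was higher in the knockout, was left out of those markers. For a smaller share of recent monocytes the values are mixed. The monocyte identity list had a median of -0.127 (quartiles -0.351 and -0.00941), little beside the -1.04 of class II, but it also holds genes of macrophages, and Ccr2 moved with class II between replicates in 4 of 4 groups (Ccr2 at 32.5 ± 11 CPM in the untreated wild type and 16.8 ± 6.6 in the knockout). Class II and Ccr2 each moved the same way in the untreated and treated libraries of a genotype. Counts over the 4 groups may therefore not rest on 4 separate checks. The genotype was not tested apart from the shares of these cells.

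The longer STAT1 peak list of untreated knockout PEC is unlikely to come from depth or from background at random places. The library had 1.04 times the tags of the untreated wild type, and its peaks overlapped treated wild-type peaks 8.88 times as often as the moved ones did among those absent from the untreated wild type (93.5 and 10.5% of 8337 peaks). Moved peaks stand for randomly placed background alone, so unspecific signal at places that recur between libraries was not excluded. Carry-over of treated chromatin would reach the strongest treated knockout peaks before weak ones. The overlap with untreated knockout peaks did fall with the treated score, at 40.3, 38.3, 23.1, 13.2 and 6.56% from the top quintile to the lowest. Yet among treated knockout peaks without an untreated wild-type peak, 45.4% of the 1% with the most tags had an untreated knockout peak (95% interval 40.4 to 50.4%), while 8.30% of the lowest quintile had one, so carry-over does not account for the whole list. With 1 library per group a difference in immunoprecipitation could give the same picture, and the genotype was not tested apart from it.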
